A study of Rattus norvegicus with 9 samples.

How the data were processed

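Small RNA libraries were made from retinas of Sprague Dawley rats, dissected from the eye, with RNA isolated by a column kit that keeps miRNA and sequenced as 50 bp single-end reads, per the labels' protocols. The sequencer is a HiSeq 2000 per the labels' protocols and a HiSeq 2500 per the series text, and the difference was not resolved. The read trimming, aligner, counter, genome build and miRNA annotation are not given in the sources used here, so no genome coordinates are printed. The authors deposited 2 tables, 1 for each of their comparisons, each with read counts per mature miRNA for 6 libraries, per the file headers. Both tables list the same 465 miRNAs, and the rule by which low-count miRNAs may have been left out is not given in the sources used here. The authors also deposited a log2 fold, a p-value and a false discovery rate per miRNA in each table, per the file headers. limma is the tool named, without a version, per the submitters' processing notes. The authors' deposited counts are whole numbers that sum to different totals in each library, so they were used as raw counts and their own folds and p-values served only as an alternative.

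The 12 library columns hold 9 libraries, because the OIR P14 libraries stand in both tables with 1395 of 1395 identical counts. Columns carry library codes and no group names. The group of each code was deduced from the tables in which it stands: codes present in both tables (11, 12 and 38) are OIR P14, the other codes of the P14 comparison (25, 27 and 51) are sham P14, and the other codes of the second table (20, 21 and 47) are OIR P29. The signs of the authors' deposited folds matched this grouping for 7 of 7 and 198 of 198 miRNAs called here. Which code belongs to which numbered replicate of the labels is not given, so replicates were never paired. Replicates of a group differed by more than counting noise (chi-square per degree of freedom from 14.3 to 127), and none looked like a library counted more than once. OIR P14 libraries 11 and 12 (23.9) were closer to each other than to library 38 (73.5 and 69.0). OIR P29 libraries 20 and 21 (14.3) were likewise closer to each other than to library 47 (110 and 99.3). The reason is not given, and the tests treat the 3 libraries of a group as equally independent, which they may not be. Names with identical counts were searched with a tolerance of 1% of their totals, which found 5 pairs among 7 names. The reference table of gene names was not used here, since the tables give miRNA names.

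Each comparison was fitted to its own 6 libraries with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15, the quasi-likelihood F test with 4 residual degrees of freedom and Benjamini-Hochberg adjustment, called at adjusted p under 0.05. The filter left 415 miRNAs at P14 and 424 for P29 against P14, leaving out 50 and 41. The standard error of a log2 fold is its size over the square root of F. The biological coefficient of variation was 14.6% and 17.6%, and the median standard error of the log2 fold 0.165 and 0.151. Lists were tested with limma 3.58.1's camera test, 2-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists with at least 3 measured members. The pipeline was tested on simulated data with 200 changed miRNAs and 10 draws for each comparison. At P14 (422 miRNAs) it recovered 65.2% of 1.5-fold, 91.3% of 2-fold and 99.5% of 4-fold changes with 2.60% false calls. For P29 against P14 (429 miRNAs) it recovered 59.5%, 89.8% and 99.7% with 2.87% false calls. The 200 simulated changes far outnumber the 7 miRNAs called at P14, and the adjustment is stricter when fewer miRNAs change. Recovery at P14 may therefore be lower than these figures. The simulation also balanced rises with falls, left miR-182 unchanged and drew every replicate independently. Its share of false calls may therefore not hold for these data.

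The groups, comparisons, lists, the rule for named miRNAs and most alternatives were set before the data were examined. Named miRNAs are the 10 largest folds in each direction among called miRNAs whose groups do not overlap, or the smallest p values up to 5 in a direction with fewer. The rule adds the 8 most abundant miRNAs and a fixed set linked to hypoxia, vessels, inflammation, neurons, photoreceptors and pigment epithelium, of which miR-206 had no measured value. Members given as examples of a list are those with the smallest p. The 15 lists were the sensory cluster, neuronal, progenitor timing, glia and pigment epithelium, hypoxia, endothelial and angiogenesis, miR-17 to 92 family, mural cell and fibroblast, leukocyte and microglia, erythroid, muscle, epithelium, the imprinted Dlk1-Dio3 cluster, and the lists raised and lowered in ischemic retina. Lists overlap: miR-150, for example, is in the endothelial, leukocyte and ischemic lowered lists. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, centring on the median miRNA, quantile normalization with limma-voom, each library left out, adjusted p under 0.1 and 0.01, folds of at least 1.5 and 2, the authors' deposited p-values, and an estimated correlation in camera. Added after the data were seen were limma-voom with TMM, library totals alone, removal of the 3 most abundant miRNAs, all 9 libraries in 1 fit, a block for library codes above or below 30, the comparison of OIR P29 with sham P14 and the correlation of the 2 folds without single libraries. Opposite movement was set beside 100 simulated draws of unchanged groups that share the OIR P14 libraries. Figures were drawn with matplotlib 3.10.9. No retina from sham animals at P29 was analysed here.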

Results

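Mature miRNAs were counted by small RNA sequencing of dissected retinas from Sprague Dawley rats in 3 groups of 3 libraries. The groups were sham animals at postnatal day 14 (sham P14), animals with oxygen-induced retinopathy at the same age (OIR P14) and animals with the retinopathy at postnatal day 29 (OIR P29). Oxygen-induced retinopathy is a rodent model of retinopathy of prematurity, in which exposure of newborn animals to altered oxygen stops the growth of retinal vessels and is followed by abnormal vessel growth. Total counts per library were 11808893 to 12568341 in sham P14, 12694068 to 15260603 in OIR P14 and 13088233 to 13973950 in OIR P29, over the same 465 mature miRNAs. Between 463 and 465 of them had at least 1 count in a library, and a count of 0 allows a level of up to 0.197 to 0.254 CPM (counts scaled to a common library size), taken as 3 counts of the total. Intervals and such limits cover counting error only. The labels call the samples biological triplicates without saying whether a library held 1 animal or a pool, so p-values measure the spread between these libraries.

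miR-182, a member of the miR-183/96/182 cluster abundant in photoreceptors, took most of the reads in every library. Its share was 63.3% ± 0.894 in sham P14, 66.5% ± 1.53 in OIR P14 and 60.4% ± 1.22 in OIR P29 (SD, n = 3 each). Together with miR-181a-5p and miR-183-5p it took 82.7% ± 1.0, 84.1% ± 1.0 and 78.2% ± 0.988 of the reads in the same order (SD, n = 3 each). The next most abundant miRNAs were miR-204-5p, miR-26a-5p, miR-9a-5p, miR-30a-5p and miR-191a-5p. CPM values below come from 1 normalization of all 9 libraries, and folds come from the fit of each comparison to its own 6 libraries. Some counts were shared between names: miR-129-1-3p and miR-129-2-3p had identical counts in 6 of 9 libraries, and let-7a-1-3p and let-7c-2-3p in 8 of 9. The 3 names miR-3084a-3p, miR-3084b-3p and miR-3084d had identical counts in 9 of 9 libraries, so the values of these near-identical copies are uncertain.

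The comparison of OIR P14 with sham P14 asked which retinal miRNAs differ between the retinopathy and control animals of the same age. Both arms of miR-126a, a miRNA of endothelial cells, were lower in OIR P14: miR-126a-3p fell from 144 ± 4.98 to 46.7 ± 16.1 CPM and miR-126a-5p from 510 ± 55.4 to 187 ± 58.5 CPM (SD, n = 3 each). miR-143-3p, made in smooth muscle cells and pericytes, fell from 1166 ± 85.0 to 427 ± 165 CPM, and miR-145-3p, from the same gene cluster, fell from 4.34 ± 0.913 to 1.72 ± 0.476 CPM (SD, n = 3 each). miR-150-5p, abundant in lymphocytes, fell from 23.3 ± 3.76 to 6.57 ± 1.78 CPM, and miR-451-5p, abundant in red blood cells, fell from 5.13 ± 1.69 to 1.22 ± 0.201 CPM (SD, n = 3 each). miR-1224, made from a short intron, fell to 8.45 ± 0.242 CPM (SD, n = 3). As folds, miR-451-5p was 4.21 times lower (log2 fold -2.07 ± 0.31 SE), miR-150-5p 3.56 times (-1.83 ± 0.20) and miR-126a-3p 3.10 times (-1.63 ± 0.21). miR-143-3p was 2.75 times lower (-1.46 ± 0.22), miR-126a-5p 2.74 times (-1.45 ± 0.20), miR-145-3p 2.52 times (-1.33 ± 0.25) and miR-1224 1.79 times (-0.84 ± 0.15).

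These 7 were all that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment among 415 miRNAs tested, with adjusted p from 0.00357 for miR-150-5p to 0.0291 for miR-145-3p. All 3 OIR P14 libraries lay below all 3 sham P14 libraries for each of the 7. Without any adjustment 38 miRNAs had p under 0.05, 12 higher and 26 lower, and 63 of the 415 (15.2%) had groups that did not overlap, where chance gives 10%. edgeR called 0 miRNAs higher in OIR P14, limma-voom also 0, and DESeq2 called 14 in all, of which 1 was higher (miR-1247-5p). miR-1247-5p had a log2 fold of 1.44 ± 0.36 SE with adjusted p = 0.124 in edgeR and 0.00128 in DESeq2, within a range of 0.00128 to 0.489 over 16 alternatives. The other miRNAs with the smallest p among those with a positive fold were miR-6329 (log2 fold 0.57), miR-142-5p (0.47), miR-484 (0.40) and miR-1249 (0.31), with edgeR adjusted p from 0.208 to 0.393. Most calls, though not the folds, were lost when a sham library was left out: without sham P14 library 27, or without sham P14 library 51, miR-150-5p alone stayed below the threshold (1 call each), the other 6 having edgeR adjusted p from 0.0517 to 0.231. The log2 folds without library 27 and without library 51 were -1.90 and -1.97 for miR-451-5p, -1.62 and -1.63 for miR-126a-3p and -1.41 and -1.47 for miR-143-3p. Among the OIR P14 libraries, miR-145-3p lost its call without library 11 (edgeR adjusted p = 0.199) or 12 (0.182), miR-1224 without library 12 (0.113) or 38 (0.0648), and miR-451-5p without library 38 (0.0598). miR-145-3p also lost it without sham P14 library 25 (edgeR adjusted p = 0.147), and leaving out OIR P14 library 11 gave 7 calls, 1 of them higher. Quantile normalization with limma-voom left 2 calls, miR-150-5p and miR-126a-3p, the other 5 having adjusted p from 0.067 to 0.0708. miR-145-3p was not called with a block for library codes (edgeR adjusted p = 0.0807), nor miR-1224 with all 9 libraries fitted together (0.0768). Over 16 alternatives the edgeR, DESeq2 or limma adjusted p spanned 0.00128 to 0.113 for miR-1224, 0.00785 to 0.231 for miR-145-3p and 1.3e-05 to 0.0708 for miR-451-5p. The authors' deposited table called 10 miRNAs lower and 0 higher at the same threshold, 6 of them shared with the 7. It added miR-1298, miR-134-5p, miR-145-5p and miR-322-5p, whose adjusted p here in edgeR was from 0.0923 to 0.133, and left out miR-1224 (0.0668 in the authors' deposited table).

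**Figure D1:**
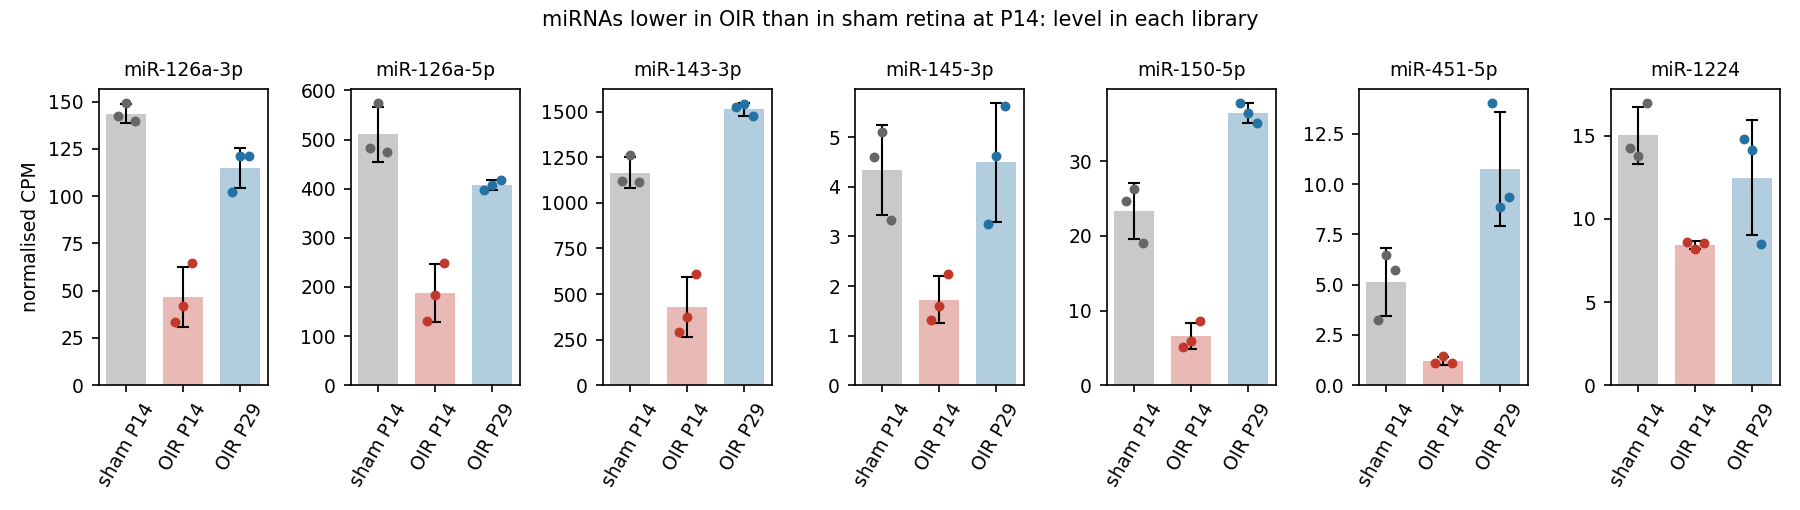
Normalised level (CPM, linear axis from 0) of the 7 miRNAs called lower in OIR P14 than in sham P14, with 1 point per library, bars at the group mean and error bars of 1 SD (n = 3). For miR-126a-3p the means were 144 CPM in sham P14, 46.7 in OIR P14 and 115 in OIR P29, and for miR-150-5p they were 23.3, 6.57 and 36.5.

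miR-210-3p, a target of hypoxia-inducible factor, stood at 195 ± 8.58 CPM in sham P14 and 156 ± 5.77 CPM in OIR P14 (SD, n = 3 each), a log2 fold of -0.33 ± 0.10 SE that did not pass the test (edgeR adjusted p = 0.208). miR-182 (log2 fold 0.26 ± 0.12) and miR-204-5p (0.58 ± 0.29), a miRNA of the pigment epithelium, were not called either, with edgeR adjusted p of 0.535 and 0.565. The inflammation-linked miR-21-5p (log2 fold -0.01), miR-146a-5p (-0.34) and miR-155-5p (-0.24) had edgeR adjusted p of 0.948, 0.588 and 0.841. Also not called were miR-132-3p (log2 fold -0.02), miR-34a-5p (-0.15), the neuronal miR-124-3p (0.05), miR-96-5p (0.23), miR-183-5p (0.13), miR-211-5p (0.00) and miR-31a-5p (0.17). miR-184 varied widely between libraries (61.0 ± 66.2 CPM in sham P14, SD, n = 3) and its log2 fold of -0.54 ± 0.69 SE was not called and ran from -0.94 to 0.93 over 16 alternatives. Precision was lower for scarce miRNAs: the median SE of the log2 fold was 0.272 for 61 miRNAs with a mean count under 30 and 0.116 for 116 miRNAs above 1000.

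Of 15 lists of miRNAs fixed beforehand, 6 moved as a set at P14 by limma's camera test with a preset correlation, and 0 of them at adjusted p under 0.05 with an estimated correlation. The latter setting also lowers camera's degrees of freedom to the 4 of the fit, which raises p by itself. The erythroid list and the list lowered in ischemic retina had estimated correlations of -0.155 and -0.272, below the preset 0.01. Their unadjusted camera p still rose from 0.0131 to 0.0657 and from 0.00338 to 0.0408. The lost calls therefore cannot be put down to correlation between members. The mural cell and fibroblast list fell (camera adjusted p = 0.00126; adjusted p = 0.287 with an estimated correlation), with 2 of 12 members lower, 10 not called and 4 lower when adjusted over the list alone. Its leading members were miR-143-3p, miR-145-3p and miR-145-5p (log2 fold -1.28 ± 0.33, edgeR adjusted p = 0.133). The erythroid list fell (0.0347; adjusted p = 0.287 with an estimated correlation) through miR-451-5p, 1 of 3 members lower and 1 when adjusted over the list alone, while miR-486 had a log2 fold of -0.11 ± 0.08 and miR-363-3p of 0.04. Both arms of miR-144, also of this list, were left out by the filter. Without it miR-144-3p had a log2 fold of -1.65 ± 0.595 and miR-144-5p of -1.74 ± 0.532, not called (edgeR unadjusted p = 0.0228 and 0.0103, adjusted p = 0.369 and 0.252). The list reported as lowered in ischemic retina, recalled from an earlier mouse study and not drawn from these samples, fell (0.0253; adjusted p = 0.287 with an estimated correlation) with 1 of 3 members lower, miR-150-5p, and 1 when adjusted over the list alone. The imprinted Dlk1-Dio3 cluster, expressed in neurons, fell as a set (0.0347; adjusted p = 0.338 with an estimated correlation), with 55 of 70 members negative and a median log2 fold of -0.12, which was -0.30 with libraries scaled on their totals alone and -0.04 with quantile normalization. edgeR called 0 of its members, over all miRNAs and when adjusted over the list alone, 4 were lower at an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 0. With totals alone edgeR called 1 member lower. Its leading members were miR-134-5p (log2 fold -0.55 ± 0.13, edgeR adjusted p = 0.0969) and miR-409a-3p (-0.34 ± 0.10, 0.181).

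In the opposite direction, the sensory cluster rose as a set (camera adjusted p = 0.0347; adjusted p = 0.287 with an estimated correlation), with all 5 members positive and a median log2 fold of 0.23 that shrank to 0.05 with totals alone and 0.03 with quantile normalization, led by miR-183-3p (log2 fold 0.33 ± 0.12, edgeR adjusted p = 0.393) and miR-182. Quantile normalization sets the log2 fold of miR-182, the top miRNA of every library, to 0 by its construction, so part of that shrinkage is built in. The proliferation-linked miR-17 to 92 family rose as a set (0.0285; adjusted p = 0.323 with an estimated correlation), with 18 of 22 members positive and a median log2 fold of 0.19 that became -0.0041 when libraries were scaled on their totals alone. Its leading members were miR-20b-3p (log2 fold 0.70 ± 0.25, edgeR adjusted p = 0.454) and miR-18a-3p (0.53 ± 0.25, 0.554). edgeR called 0 members of either list, also when adjusted over the list alone, with 1 member of each higher at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Scaling on totals moved the median log2 fold of all miRNAs at P14 from -0.03 to -0.21. Several of the 6 sets lost their camera call without 1 library. Without sham P14 library 25 these were the sensory cluster (camera adjusted p = 0.0612), the miR-17 to 92 family (0.0934) and the Dlk1-Dio3 cluster (0.169). Without library 27 they were the erythroid list (0.0728) and the Dlk1-Dio3 cluster (0.0531), and without library 51 the sensory cluster (0.137), the erythroid list (0.137) and the list lowered in ischemic retina (0.175). Without OIR P14 library 11 they were the sensory cluster (0.12), the miR-17 to 92 family (0.0531) and the Dlk1-Dio3 cluster (0.12), and without library 38 the list lowered in ischemic retina (0.0821). That list was also lost with no filter on low counts (0.101) and with all 9 libraries fitted together (0.122), and the sensory cluster and Dlk1-Dio3 cluster were lost when libraries were centred on their median miRNA (0.0528 each). Over 10 alternatives the camera adjusted p had highest values of 0.287 to 0.338 for the 6 sets, all from the estimated correlation, and lowest values from 4.16e-07 for the erythroid list to 0.026 for the sensory cluster.

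Among the 9 lists not called at P14, the endothelial and angiogenesis list (camera adjusted p = 0.096) held 3 of 38 members lower, miR-150-5p, miR-126a-3p and miR-126a-5p, and 4 when adjusted over the list alone, miR-322-5p being the fourth. Its median log2 fold was 0.0015 while its mean was -0.18 and the test pointed down. The list raised in ischemic retina (0.096) had 1 of 16 members lower, miR-451-5p, and 2 when adjusted over the list alone, and passed without sham P14 library 27 (0.0387; range 0.0387 to 0.693 over 10 alternatives). The epithelium list (0.096) had 0 of 6 members called, led by miR-203a-3p (log2 fold 0.57 ± 0.22), and passed without OIR P14 library 12 (0.00602; range 0.00602 to 0.349). The leukocyte and microglia list (0.478) had 1 of 12 lower, miR-150-5p, and 1 when adjusted over the list alone, while miR-142-5p and miR-142-3p had positive log2 folds of 0.47 and 0.38. edgeR called 0 members of the neuronal (42 measured, camera adjusted p = 0.955), glia and pigment epithelium (35, 0.236), progenitor timing (27, 0.734), hypoxia (10, 0.769), muscle (4, 0.734) and epithelium lists. That count was also 0 when adjusted over the list alone and in DESeq2 and limma-voom, and at an unadjusted p under 0.05 these lists held 1, 0, 2, 1, 0 and 1 members in the same order.

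The comparison of OIR P29 with OIR P14 followed the retinopathy retina to the later age, with age and stage of the model changing together. miR-29a-3p, a miRNA that represses collagen genes and is found in glia, rose from 71.9 ± 10.2 to 537 ± 37.3 CPM, and miR-132-3p, induced by neuronal activity, from 14.0 ± 1.28 to 66.4 ± 3.50 CPM (SD, n = 3 each). miR-451-5p rose from 1.22 ± 0.201 to 10.8 ± 2.85 CPM and miR-150-5p from 6.57 ± 1.78 to 36.5 ± 1.30 CPM (SD, n = 3 each). In the other direction miR-298-5p fell to 26.4 ± 1.45 CPM and miR-301b-3p from 26.5 ± 3.55 to 5.90 ± 0.408 CPM (SD, n = 3 each). The vessel-associated miR-126a-3p, miR-126a-5p, miR-143-3p and miR-145-3p were all higher at P29, with log2 folds of 1.26 ± 0.21, 1.08 ± 0.19, 1.79 ± 0.22 and 1.35 ± 0.28 SE. miR-210-3p rose from 156 ± 5.77 to 295 ± 19.3 CPM (SD, n = 3 each), a log2 fold of 0.88 ± 0.08 SE.

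edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 198 of 424 miRNAs, 97 higher and 101 lower at P29, and for 196 of the 198 the 2 groups of libraries did not overlap. Over all 424 miRNAs, 235 had an unadjusted p under 0.05 and 246 (58.0%) had groups that did not overlap, where chance gives 10%. With libraries scaled on their totals alone the calls numbered 201, 148 higher and 53 lower, since that scaling moved the median log2 fold from -0.01 to 0.25. At least a 2-fold change was seen for 65, 33 higher and 32 lower. The authors' deposited table called 191, of which 182 were shared. The 10 largest rises after the groups were required not to overlap were miR-451-5p (8.44-fold), miR-29b-3p (7.62), miR-29a-3p (7.24), miR-144-3p (6.58), miR-144-5p (6.36), miR-150-5p (5.39), miR-212-3p (5.33), miR-7b (4.73), miR-132-3p (4.59) and miR-29a-5p (4.57). Their SEs on the log2 scale ran from 0.09 to 0.49 and their edgeR adjusted p from 4.46e-06 for miR-29a-3p and miR-132-3p to 0.00342 for miR-144-5p. The 10 largest falls were miR-296-3p (5.71 times lower), miR-412-3p (5.13), miR-770-3p (4.76), miR-301b-3p (4.67), miR-298-5p (4.61), miR-18a-5p (3.61), miR-130b-3p (2.97), miR-130b-5p (2.91), miR-216b-5p (2.66) and miR-18a-3p (2.65). Their SEs ran from 0.12 to 0.34 and their edgeR adjusted p from 5.07e-05 for miR-298-5p to 0.00551 for miR-216b-5p. Of these 20, 7 had a mean under 1 CPM in their lower group, close to the limit of a count of 0: miR-144-5p (0.289 CPM), miR-29a-5p (0.496), miR-144-3p (0.523) and miR-7b (0.833) in OIR P14, and miR-296-3p (0.299), miR-412-3p (0.534) and miR-18a-3p (0.736) in OIR P29. Their SEs ran from 0.26 to 0.49.

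Among the most abundant miRNAs, miR-182 fell (log2 fold -0.42 ± 0.11, edgeR adjusted p = 0.0143), as did miR-9a-5p (-0.41 ± 0.07, 0.00237) and miR-183-5p (-0.41 ± 0.09, 0.00701). With totals alone miR-183-5p and miR-9a-5p were no longer called (log2 folds -0.13 and -0.15, edgeR adjusted p = 0.235 and 0.273), within ranges of 0.000449 to 1 and 4.9e-05 to 0.273 over the alternatives. miR-30a-5p (0.52 ± 0.08), miR-26a-5p (0.47 ± 0.09) and miR-204-5p (0.51 ± 0.15) rose, the last with edgeR adjusted p = 0.0268, lost with centring on the median miRNA (0.0743; range 0.000793 to 1) or all 9 libraries in 1 fit (0.0991). miR-211-5p, a pigment epithelium miRNA, rose (0.74 ± 0.06, edgeR adjusted p = 0.000107), and miR-96-5p rose (0.33 ± 0.10, 0.0269) against the fall of miR-182, a partner in its cluster. The other arms, miR-211-3p (log2 fold -0.12, edgeR adjusted p = 0.564) and miR-96-3p (-0.38, 0.102), had negative folds and were not called. miR-96-5p lost its call with centring on the median miRNA (0.0938; range 0.000408 to 0.0938). Quantile normalization sets the log2 folds of miR-182, miR-183-5p, miR-204-5p and miR-26a-5p to 0 by its construction, since their ranks stayed in place. miR-191a-5p (-0.07), miR-146a-5p (0.26), miR-155-5p (-0.27) and miR-34a-5p (0.47) were not called, with edgeR adjusted p of 0.514, 0.316, 0.584 and 0.0851. miR-34a-5p was called with totals alone (edgeR adjusted p = 0.0399) and with a block for library codes (0.0182), and miR-191a-5p with quantile normalization and limma-voom (0.00924).

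miR-181a-5p (log2 fold -0.18), miR-21-5p (0.14) and miR-124-3p (0.36) were not called at P29 with all libraries, with edgeR adjusted p of 0.201, 0.142 and 0.052, and each crossed the threshold when 1 library was left out. Without OIR P14 library 38 the adjusted p in edgeR was 0.0454 for miR-181a-5p and 0.00396 for miR-124-3p, and without OIR P29 library 47 it was 0.0435 for miR-21-5p. miR-124-3p was also called by DESeq2 (adjusted p = 0.0221) and limma-voom (0.0441), and in edgeR with totals alone (0.0296), the 3 most abundant miRNAs removed (0.0491) or a block for library codes (0.0163). The other arm, miR-124-5p, went the opposite way and was called (log2 fold -0.53, edgeR adjusted p = 0.00156). miR-21-5p was called with totals alone (edgeR adjusted p = 0.00707) and with the 3 most abundant removed (0.0485). Over the alternatives the adjusted p in edgeR, DESeq2 or limma spanned 0.0454 to 1 for miR-181a-5p, 0.00707 to 0.618 for miR-21-5p and 0.00396 to 0.28 for miR-124-3p. miR-184 had the largest log2 fold, 3.92 ± 1.68 SE, which was not called (edgeR adjusted p = 0.0894), and OIR P29 library 47 held 1944 CPM, against 14.3 to 137 CPM in the other 8 libraries. Without that library its log2 fold was -0.77, and without library 20 or 21 it was 4.53 or 4.51 and called (edgeR adjusted p = 0.0341 and 0.0453; range 0.0341 to 0.841). miR-31a-5p (1.10 ± 0.39, edgeR adjusted p = 0.0521) was also highest in library 47 and passed without library 20 (0.0377), 21 (0.0132) or 47 (log2 fold 0.51, 0.0192; range 0.0132 to 0.139). It was called too with DESeq2 size factors in edgeR (0.0485), centring on the median miRNA (0.0391), totals alone (0.0209), the 3 most abundant removed (0.0453) and all 9 libraries in 1 fit (0.0165).

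Of the 15 lists, 3 moved as a set between P14 and P29 by camera, and 0 of them with an estimated correlation, which also lowers the degrees of freedom. The miR-17 to 92 family fell (camera adjusted p = 0.000133; adjusted p = 0.346 with an estimated correlation), with 14 of 22 members lower, 0 higher and 8 not called, and 14 lower when adjusted over the list alone. Its median log2 fold was -0.88, and with totals alone it was -0.60 with 11 lower and 1 higher. miR-106b-5p (log2 fold -1.24 ± 0.10), miR-19a-3p (-1.26 ± 0.11), miR-19b-3p (-1.01 ± 0.09) and miR-18a-5p (-1.85 ± 0.21) led it, with edgeR adjusted p from 0.000107 to 0.000509. The 0 higher in edgeR stood beside 0 in DESeq2 and limma-voom and 1 at an unadjusted p under 0.05. The neuronal list rose (0.047; adjusted p = 0.483 with an estimated correlation), with 14 of 43 members higher, 4 lower and 25 not called, and 13 higher and 4 lower when adjusted over the list alone. With totals alone its median went from 0.18 to 0.45, with 20 members higher and 2 lower. miR-132-3p, miR-212-3p and miR-132-5p (log2 folds 2.20, 2.42 and 2.08) led the rises and miR-488-3p the falls (-1.07 ± 0.08, edgeR adjusted p = 6.86e-05), and miR-129-1-3p and miR-129-2-3p, which share their counts, are 2 of the called members. The Dlk1-Dio3 cluster fell (0.0456; adjusted p = 0.483 with an estimated correlation), with 26 of 69 members lower, 8 higher and 35 not called, and 28 lower and 9 higher when adjusted over the list alone. miR-770-3p (log2 fold -2.25 ± 0.18) and miR-410-3p (-0.82 ± 0.10) led its falls and miR-376b-3p (0.70 ± 0.10) its rises. With totals alone the median of the Dlk1-Dio3 cluster went from -0.29 to -0.03, with 12 members higher and 11 lower. Without OIR P14 library 11 the neuronal list was not called (0.0792), nor with no filter on low counts (0.0596; range 0.0234 to 0.483 over 10 alternatives), and the Dlk1-Dio3 cluster was not called without OIR P14 library 38 (0.116) or OIR P29 library 47 (0.149; range 0.0181 to 0.483).

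**Figure D2:**
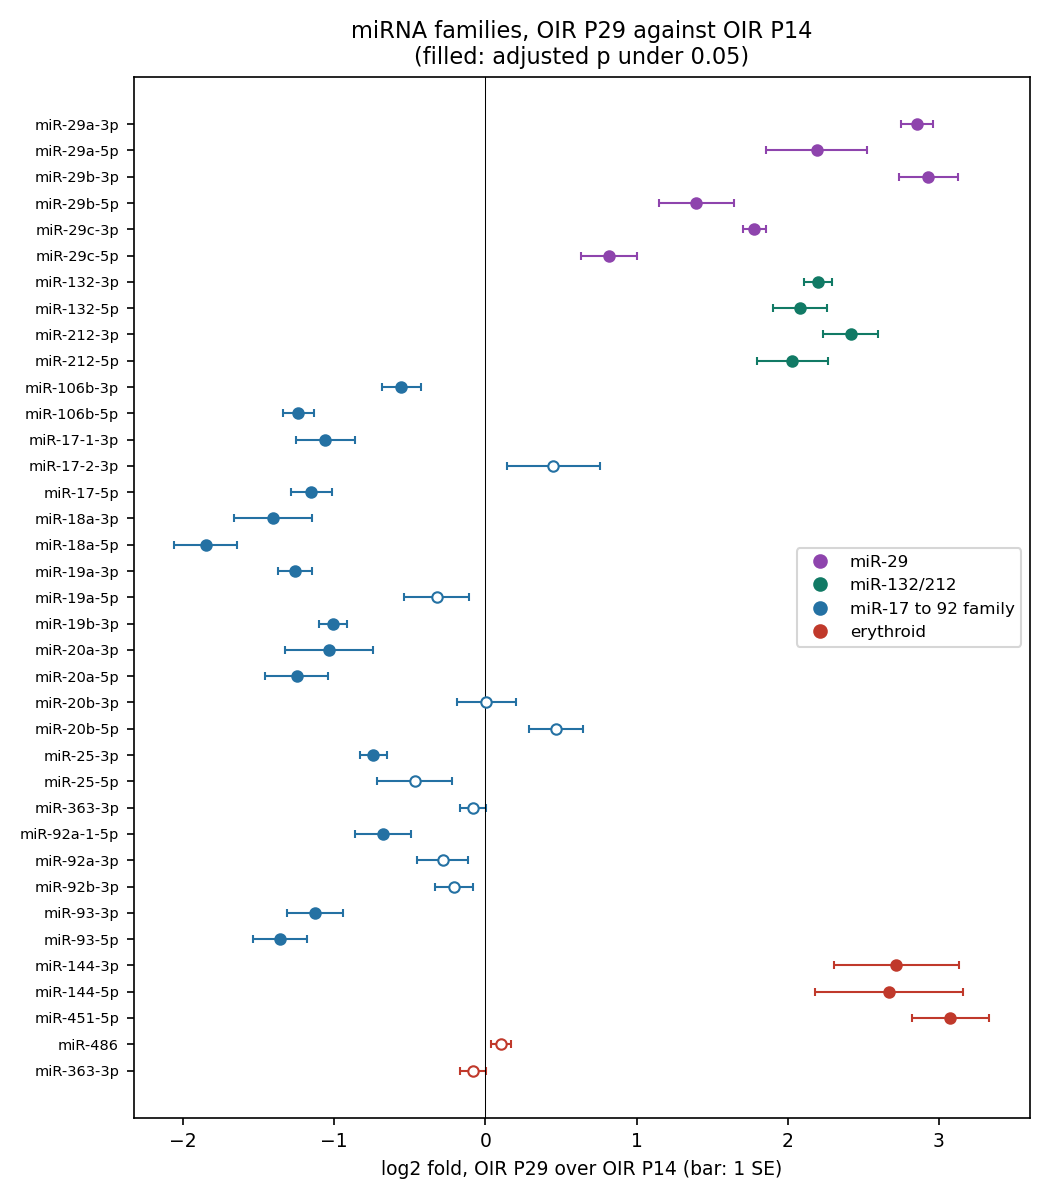
Log2 fold of OIR P29 over OIR P14 for members of 4 miRNA groups, with error bars of 1 SE (n = 3 libraries per group) and filled points at edgeR adjusted p under 0.05. All 6 arms of miR-29a, miR-29b and miR-29c lay above 0, from 0.82 to 2.93, and 14 of 22 members of the miR-17 to 92 family were filled and below 0, down to -1.85.

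The glia and pigment epithelium list did not move as a set (camera adjusted p = 0.159), with members going both ways, 14 of 36 higher and 7 lower, or 14 and 8 when adjusted over the list alone, and 20 and 3 with totals alone. All 6 measured arms of the miR-29 family were higher, from miR-29c-5p (log2 fold 0.82 ± 0.18) to miR-29b-3p (2.93 ± 0.20), while miR-181c-3p (-1.13 ± 0.09) was lower. The mural cell and fibroblast list (0.159) had 5 of 12 members higher and 5 when adjusted over the list alone, led by miR-143-3p, miR-497-5p (log2 fold 0.66 ± 0.10) and miR-195-5p (0.89 ± 0.16). edgeR and limma-voom with TMM called 0 of its members lower and DESeq2 1, 2 were lower at an unadjusted p under 0.05, and 2 were called lower with centring on the median miRNA or with quantile normalization. The endothelial and angiogenesis list (0.411) had 12 of 40 higher and 11 lower, or 13 and 11 when adjusted over the list alone and 17 and 8 with totals alone, led by miR-150-5p, miR-15b-5p (-1.32 ± 0.13) and miR-17-5p (-1.15 ± 0.14). The erythroid list (0.0973) had 3 of 5 higher, miR-451-5p, miR-144-3p and miR-144-5p, and 3 when adjusted over the list alone. It passed with centring on the median miRNA (0.0268), with all 9 libraries in 1 fit (0.048) and without OIR P29 library 20 (0.0353) or 21 (0.0253; range 0.0253 to 0.483). The leukocyte and microglia list (0.117) had 4 of 13 higher and 4 when adjusted over the list alone, miR-132-3p, miR-150-5p, miR-132-5p and miR-146b-5p (log2 fold 0.60 ± 0.12), and passed with centring (0.0234), with 9 libraries (0.048) and without library 47 (0.0464; range 0.0234 to 0.483). The arms of miR-132 are in the neuronal list too, and miR-142-5p (log2 fold 0.06) and miR-142-3p (-0.07) were not called. The hypoxia list (0.411) had 4 of 10 higher and 4 when adjusted over the list alone, led by miR-210-3p and miR-26a-5p, with a median log2 fold of 0.016 that became -0.056 with centring on the median miRNA. Of its members 3 were higher and 1 lower with centring, 1 and 1 with quantile normalization, 4 and 1 by DESeq2, and 4 and 0 by limma-voom with TMM. The progenitor timing list (0.271) had 5 of 27 higher and 2 lower, or 4 and 1 when adjusted over the list alone, including let-7c-5p (0.49 ± 0.07) and miR-9a-5p, and with totals alone 12 were higher and 0 lower. The sensory cluster (0.271) had 1 of 5 higher, miR-96-5p, and 3 lower, miR-183-3p (-0.61 ± 0.13), miR-183-5p and miR-182, with the same counts when adjusted over the list alone. With centring on the median miRNA 0 of the 5 were higher and 4 lower.

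The list raised in ischemic retina (camera adjusted p = 0.159) had 2 of 16 members higher and 6 lower at P29, with the same counts when adjusted over the list alone, led by miR-451-5p (higher) and miR-181c-3p and miR-181a-1-3p (lower), and with totals alone 3 were higher and 3 lower. The list lowered in ischemic retina (0.117) had 1 of 4 higher, miR-150-5p, and 1 when adjusted over the list alone, and passed with centring (0.0234), with 9 libraries (0.048) and without OIR P29 library 21 (0.0253; range 0.0234 to 0.483). Its other members, miR-184, miR-31a-5p and miR-31a-3p, were not called. All were highest in OIR P29 library 47, at 14.2, 2.38 and 2.66 times the highest other library. The muscle list (0.869) had 1 of 4 higher, miR-499-5p (log2 fold 0.72 ± 0.20), and 2 lower, miR-378a-3p (-0.51 ± 0.13) and miR-378a-5p (-0.23 ± 0.08), with the same counts when adjusted over the list alone. Its median (0.04) and mean (0.07) were positive while the test pointed down, and with totals alone 1 was higher and 0 lower. edgeR called 0 of 7 members of the epithelium list (0.306), 0 when adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, while 3 were higher with totals alone and 1 with centring on the median miRNA.

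The 2 comparisons share the OIR P14 libraries, so chance alone turns their folds against each other. Of the 7 miRNAs lower in OIR P14 than in sham P14, 6 were higher in OIR P29 than in OIR P14 (miR-451-5p, miR-150-5p, miR-126a-3p, miR-126a-5p, miR-143-3p and miR-145-3p) and 0 were lower, where lists drawn independently would share 1.55 and 1.72. The exception, miR-1224, had a log2 fold of 0.51 ± 0.20 at P29 that was not called (edgeR adjusted p = 0.0754). Across the 412 miRNAs tested in both, which are not independent replicates, Pearson's r between the log2 folds was -0.39 and Spearman's rho was -0.33. Simulated unchanged groups sharing those libraries gave a mean r of -0.51 (SD 0.070, lowest -0.65, 100 draws). The 2 values of r are not like for like, since real changes widen the folds and so dilute r in the data alone. The covariance was -0.103 against a simulated mean of -0.032 (SD 0.00749), a difference of -0.070 that lay beyond the spread of the draws. Splitting the OIR P14 libraries between the comparisons would leave fewer than 2 in a part, so some of the overlap may come from the sharing.

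**Figure D3:**
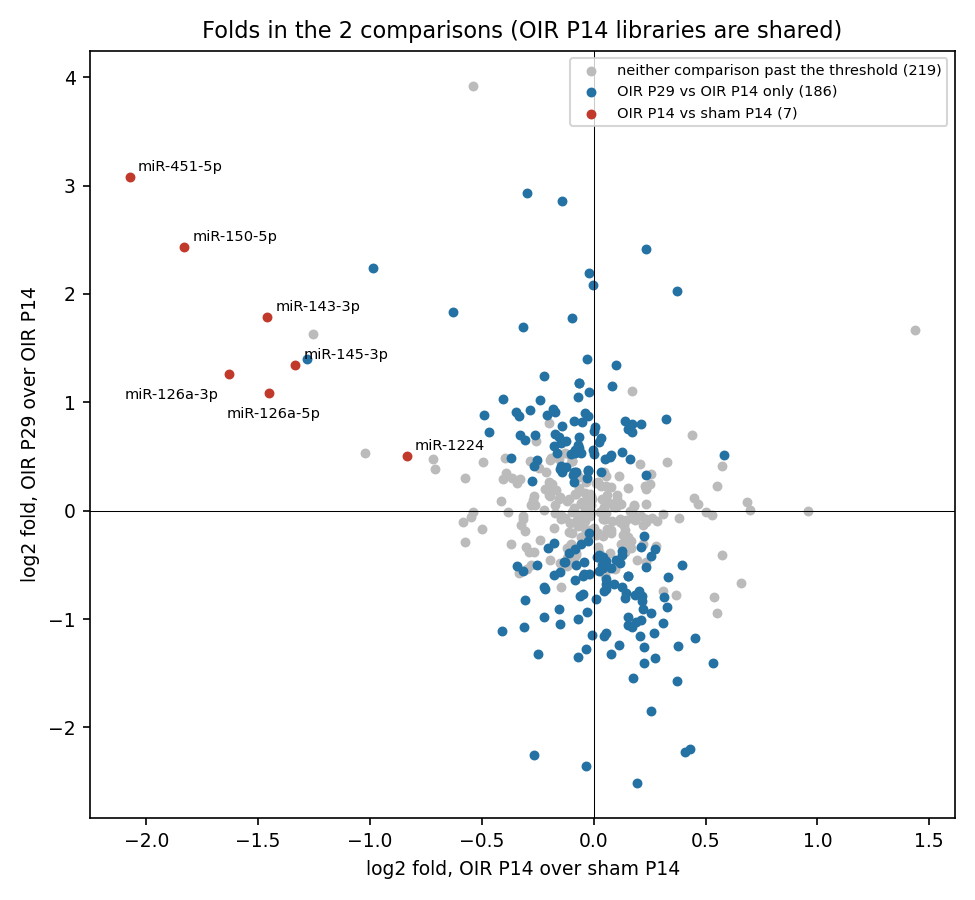
Log2 fold of OIR P29 over OIR P14 (vertical) against log2 fold of OIR P14 over sham P14 (horizontal), 1 point per miRNA tested in both comparisons (412), coloured by which comparison passed the threshold. The 7 named miRNAs lay between -2.07 and -0.84 on the horizontal axis and above 0 on the vertical axis, on axes that share the OIR P14 libraries.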

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

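Chosen only after the data were seen were the fits with limma-voom and TMM, totals alone, the 3 most abundant miRNAs removed, 9 libraries together, the library code block, and the fold correlation without single libraries. The 7 calls at P14 became 14 with DESeq2, which gave no adjusted p for 33 miRNAs, 2 with quantile normalization, 3 at adjusted p under 0.01 and 1 to 7 without single libraries. The 198 calls for P29 against P14 became 65 with a fold of at least 2, by construction, and 170 to 195 without single libraries. The 6 sets moved at P14 became 0 with an estimated correlation and 3 to 7 without single libraries. The 3 sets moved at P29 became 0 with an estimated correlation, 6 with centring on the median miRNA, 6 with 9 libraries in 1 fit and 2 to 5 without single libraries. The correlation of the 2 folds, -0.39, ran from -0.54 to -0.42 without single OIR P14 libraries. Apart from thresholds and the fewer degrees of freedom that camera uses with an estimated correlation, the cause was not tested. Every other alternative count lay within 1.5 times the main one. Named miRNAs kept direction and side of the threshold in 1007 fits, crossed it downward in 34 and upward in 24, and changed sign in 49, in each of which they were called neither before nor after. At P14 the log2 fold changed sign with totals alone for miR-181a-5p (-0.18), miR-183-5p (-0.061), miR-26a-5p (-0.024), miR-9a-5p (-0.15), miR-30a-5p (-0.18), miR-191a-5p (-0.068), miR-31a-5p (-0.0069), miR-211-5p (-0.18) and miR-124-3p (-0.12). With quantile normalization it did for miR-26a-5p (-0.068), miR-9a-5p (-0.11), miR-30a-5p (-0.076), miR-21-5p (0.00018), miR-211-5p (-0.071), miR-124-3p (-0.048) and miR-132-3p (0.0079). Centring on the median miRNA gave -0.0018 for miR-181a-5p, -0.012 for miR-30a-5p and -0.015 for miR-211-5p, DESeq2 and its size factors in edgeR gave 0.0052 each for miR-21-5p, and the library code block gave 0.069 for miR-184. Without single libraries the range at P14 was -0.12 to 0.094 for miR-181a-5p, -0.046 to 0.11 for miR-9a-5p, -0.036 to 0.048 for miR-30a-5p, -0.038 to 0.0064 for miR-21-5p, -0.73 to 0.024 for miR-155-5p, -0.94 to 0.93 for miR-184, -0.092 to 0.074 for miR-211-5p, -0.13 to 0.15 for miR-124-3p, -0.091 to 0.073 for miR-132-3p and -0.38 to 0.076 for miR-34a-5p. For P29 against P14 the sign changed with totals alone for miR-181a-5p (0.095), miR-191a-5p (0.20) and miR-155-5p (0.0020) and with quantile normalization for miR-21-5p (-0.12), and the range without single libraries was -0.11 to 0.023 for miR-191a-5p, -0.48 to 0.27 for miR-155-5p and -0.77 to 4.53 for miR-184. Lists that were not called changed direction in 15 fits: the muscle list at P29 with centring (camera adjusted p = 0.975), no filter (0.671), 9 libraries (0.992) and 5 of the 6 single libraries left out (0.668 to 0.982), and at P14, without single libraries, the neuronal list in 3 fits (0.44, 0.593 and 0.986), progenitor timing in 1 (0.719), hypoxia in 1 (0.986) and leukocyte in 2 (0.692 and 0.593). Over all 6 such fits, turned or not, these 4 spanned 0.44 to 0.986, 0.326 to 0.986, 0.519 to 0.986 and 0.205 to 0.721. Depth limits scarce miRNAs: at P29, 30.8% with a mean count under 30 were called against 55.8% above 1000, with median SE 0.293 and 0.0969. No paired analysis was possible because the columns carry library codes and no replicate numbers. Pseudocounts and limma's trend do not apply to counts fitted with edgeR and were not run.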

Other observations

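Chosen only after the result was seen were the comparison of OIR P29 with sham P14, the leukocyte, unfiltered erythroid and vessel wall tests, the test of precursor arms, and the test of epithelium in library 47.

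OIR P29 was also set against sham P14 in a fit of all 9 libraries, in which age and model differ together. edgeR's quasi-likelihood test called 181 of 432 miRNAs, 90 higher and 91 lower. Of the 7 miRNAs lower in OIR P14, miR-451-5p (log2 fold 1.06 ± 0.26 SE, edgeR adjusted p = 0.00804) and miR-150-5p (0.64 ± 0.17, 0.011) were higher in OIR P29 than in sham P14. miR-126a-3p (-0.32, 0.21) and miR-143-3p (0.38, 0.173) were not called. miR-210-3p was higher in OIR P29 (0.60 ± 0.09, edgeR adjusted p = 0.000526), as were miR-29a-3p (log2 fold 2.75) and miR-132-3p (2.23), and miR-298-5p was lower (-1.71).

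The 2 arms of a precursor mostly moved together between P14 and P29. Across 124 precursors with both arms tested, which are not independent replicates, Pearson's r between the arms' log2 folds was 0.81 and Spearman's rho 0.742 (permutation p = 1e-04, the smallest that the permutations run can give). Both arms were called for 45 precursors and shared a direction in 44, the exception being miR-369. The deviations of libraries with codes on the same side of 30 had correlations of -0.244, 0.206 and -0.0808 between groups.

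Fall of 7 miRNAs at P14: the 7, which include miR-1224 beside miRNAs of vessels and blood, had a median log2 fold of -1.46, and with miR-182, miR-181a-5p and miR-183-5p removed and libraries scaled on their median miRNA it was -1.434. That outcome was close to fixed in advance and decides nothing about reads taken by miR-182. The 7 were picked after TMM, which had already put the median log2 fold of all miRNAs at -0.0266, against -0.0387 with centring on the median miRNA. The values show only that the 7 fell relative to the other miRNAs. Less residual blood stays open for miR-451-5p: of the miRNAs named for its test, miR-144 and miR-486, miR-486 alone passed the filter and had -0.1097 ± 0.0844, past the bound written against blood beforehand, but it stood at 1086 CPM in sham P14 against 5.13 CPM of miR-451-5p, so a blood share large enough for miR-451-5p would not show in it, and miR-363-3p, also in the erythroid list and in the miR-17 to 92 family, had 0.04. Without the filter the median of miR-144-3p, miR-144-5p and miR-486 was that of miR-144-3p, -1.646 ± 0.595, which lay within 2 SE of the limit of -1.03 (0.5 times the log2 fold of miR-451-5p). miR-144-5p had -1.737 ± 0.532, and neither arm of miR-144 was called (edgeR adjusted p = 0.369 and 0.252, mean counts of 21 in sham P14 and 6.67 in OIR P14 for miR-144-3p). For the leukocyte part, the median of miR-142-3p, miR-142-5p and miR-223-3p was that of miR-142-5p, 0.4707 ± 0.163 SE, against -0.914 for 0.5 times that of miR-150-5p. The other 2 had 0.382 ± 0.236 (miR-142-3p) and 2.10 ± 0.722 (miR-223-3p), the last on mean counts of 3.33 in sham P14 and 15 in OIR P14. The absence of a fall cannot be told apart from microglia making miR-142 and miR-223 themselves. A smaller share of vessel wall cells was not settled either. Members of the endothelial list went both ways (median 0.0015, 19 of 38 positive) beside a median of -0.30 for the mural list. The endothelial list also holds miRNAs chosen for a link to angiogenesis, so its median cannot decide on a share of cells. Of the 10 splits of the 6 libraries, 1, the real one, gave 7 calls and the highest other gave 0, but 10 splits are too few for a share under 0.05.

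Change between P14 and P29: 198 miRNAs differed. Of 81 arm pairs with a called arm, 67 had the same sign (82.72%, exact binomial 95% interval 72.7 to 90.2), which argues against ligation or capture bias acting on single mature sequences as the whole cause. The interval takes the pairs as independent, which they are not, so it may be too narrow. Normal aging of the retina and the course of the retinopathy cannot be told apart, because 0 sham libraries at P29 were analysed here. Of the 10 splits, 1, the real one, gave 198 calls and the highest other gave 0, and 10 splits are too few for a share under 0.05.

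Single high library: OIR P29 library 47 had 1944 CPM of miR-184, 119 CPM of miR-1247-5p and 87.1 CPM of miR-31a-5p, against highest values of 137, 22.8 and 36.6 CPM in the other 8 libraries. Surface epithelium such as the cornea's, known for miR-184, was tested through miR-205, miR-203a-3p and miR-141-3p, whose median log2 ratio to the other OIR P29 libraries was -0.339. miR-205 and miR-141-3p lay between the 2 other OIR P29 libraries and miR-203a-3p below both, and the spread between libraries of a group is wide (SE of the ratio 2.16 for miR-205, 0.618 for miR-141-3p and 0.348 for miR-203a-3p), so surface epithelium stays open, as do lens, iris and ciliary body, which were not tested. Leaving library 47 out gave 191 calls for P29 against P14 in place of 198. No biological explanation was tested, as the labels say nothing that sets this sample apart.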
